A study of Drosophila melanogaster and Homo sapiens with 35 samples.

How the data were processed

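TRIBE marks the transcripts that an RNA-binding protein meets: the protein is fused to the catalytic domain of the RNA-editing enzyme ADAR, and edited adenosines read as A-to-G changes in RNA sequencing. The samples were Drosophila S2 cells, a line of embryonic, hemocyte-like origin, with Thor, the fly eIF4E-binding protein (4E-BP), fused to a hyperactive ADAR domain (hyperADARcd). Human PC3 prostate cancer cells carried 4E-BP1 fused to the corresponding domain of human ADAR2. Of 35 samples in the study, 20 are reported here, 13 libraries of S2 and 7 of PC3; the 15 ribosome-profiling samples were not analysed here.

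Each deposited file lists edited positions of 1 library, and its values are counts per the file headers: RNA reads with each base at the position, and genomic DNA reads with each base at the same position. The authors' notes name Trimmomatic 0.30 and the builds dm3 for S2 and hg38 for PC3; the aligner, the removal of duplicate reads and the program that called sites are not given in the sources used here. The authors deposited only sites past a threshold. All listed sites had at least 20 RNA reads, an editing level of at least 10 percent and no edited base in genomic DNA, except that hyperADARcd alone replicate 2 of S2 listed nothing under 20 percent. A position missing from a list may therefore be unedited, edited below the threshold or covered by too few reads, and no floor was computed for it. The deposited list of PC3 4E-BP1 with DMSO replicate 2 stops within a line on chromosome 7, so chromosome 6 is the last that it covers in full.

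The editing level of a site is the edited reads divided by all reads at the site, in percent, computed from the deposited base counts. A target site was listed in every library of a group and in no library with green fluorescent protein (GFP) alone or the enzyme alone; a target gene had at least 1 target site. Site numbers per library were compared by exact permutation tests, two-sided, on log2 of the number plus 1. Editing levels were compared at sites listed in all induced fusion libraries of a line with edgeR 4.0.16 quasi-likelihood F tests on edited and unedited reads, with library terms, for each site and for each gene with its tested sites summed. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Differences are given as log2 odds ratios of edited reads with a standard error (SE). Sets of genes were compared with the other tested genes by camera of limma 3.58.1, with a preset correlation of 0.01.

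The gene lists were, for both lines, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, translation factors, TOP mRNAs outside the ribosomal proteins (in S2, homologues of the human ones), aminoacyl-tRNA synthetases, ribosome biogenesis, oxidative phosphorylation, proteasome, glycolysis, chaperones, vacuolar ATPase, TOR pathway and autophagy, cell cycle, cytoskeleton and construct genes. S2 also had hemocyte, neuron, and germline and ovary markers. PC3 also had eIF4E-sensitive mRNAs, epithelial and prostate markers, and stromal and blood markers. Lists of at least 5 listed genes were tested among target genes by Fisher's exact test, two-sided, against every gene listed in any library of the line, with adjustment over lists and groups of a line. Members were matched by symbol patterns, so the human ribosomal protein list includes RPL7L1. The human translation factors include eIF2 kinases and EIF4EBP1, the gene of the fused protein. Of 3061 S2 gene names, 2377 were current symbols, 633 were matched through a synonym, 46 were ambiguous and 5 had no match.

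The genes named in the text were chosen by a rule: the genes of the construct; for each group, the 10 target genes with the most target sites, ties broken by the mean level; for each level comparison, up to 10 genes called in each direction with the groups not overlapping; and for each list, up to 4 members with the most target sites over the inhibitor groups. Samples, groups, tests, lists, this rule and the first set of alternatives were fixed before the data were examined. The alternatives were coverage of at least 40 reads, an editing level of at least 20 percent, thinning of reads to the shallowest fusion library (the median of 20 draws), sites in at least 1 replicate, at least 2 sites per gene, the uninduced fusion as an added control, leaving out each replicate, a replicate term, limma on the logit of the level (limits of 0.5 and 99.5 percent), sites of the enzyme-only libraries left out, and 3 strata of coverage for the lists. Equal library medians, 10 strata, complete PC3 libraries alone, chromosome 6 alone and tests of a list between 2 groups were added after the data had been seen.

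The level test was tested on simulated data with 148 sites, of which 40 were changed, in 10 draws. With a true log2 odds ratio of 2 it found 34.5 percent of the changed sites, and with a true value of 1 it found 4.5 percent. Over all changed sites, found or not, 96.5 percent had the right sign. The test made 0.3 false calls per draw on average. With libraries also shifted by an SD of 0.5 in log2 odds, near the 0.559 of the S2 library medians, it found 16 percent at a true value of 2 and 2 percent at 1. The list test was run on 20 simulated sets of targets: with no difference it called no set of ribosomal proteins, and with odds 4 times as high for them it called all 20. With the share of targets set by coverage alone, Fisher's exact test still called ribosomal proteins in 20 of 20 sets (median odds ratio 13.3, with 6.4 other calls on average). The test over 3 strata did so in 20 (4.23) and that over 10 strata in 0 (1.32). Intervals for a single library are Wilson intervals at 95 percent and cover counting error only. Where a gene's sites are summed, a read over several sites counts at each, so these intervals can be too narrow. Depth is limited by the lists themselves: the median coverage of a listed site was between 25.5 and 37.5 reads in every library, and no S2 site had over 150 reads outside hyperADARcd alone replicate 2. Other tools were Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.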

Results

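RNA editing by 4E-BP fusions was measured in 13 S2 libraries and 7 PC3 libraries. The S2 groups were GFP alone (1 library), hyperADARcd alone (2), uninduced Thor-hyperADARcd (2), and induced Thor-hyperADARcd with DMSO (2), rapamycin (2), rapamycin with serum withdrawn (2) or Torin-1 (2). Rapamycin and Torin-1 were given at 50 nM for 5 h. Rapamycin inhibits TOR complex 1 as an allosteric complex with FKBP12, and Torin-1 is an inhibitor of the TOR kinase site. The PC3 groups were the enzyme alone (2) and 4E-BP1 fused to the enzyme with DMSO (2), 200 nM INK128 (2) or 2.5 µM PP242 (1), both inhibitors of the mTOR kinase site. S2 libraries listed 8365 distinct sites in 3061 genes, and PC3 libraries 3329 sites in 2129 genes. The summed coverage of listed sites ran from 464 reads with GFP alone to 161895 with rapamycin without serum replicate 2 in S2. In PC3 it ran from 1921 reads in the shortened DMSO replicate 2 list to 98047 in INK128 replicate 2. Spreads below are those between replicate libraries, which may be technical.

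The comparison of the fusion with its controls asks how much editing depends on 4E-BP being attached to the enzyme. Thor, the gene of the fused protein, had an edited exonic position at dm3 2L:3478533 in all 8 induced libraries, from 24.3% of 115 reads with DMSO replicate 1 (Wilson 95% interval 17.4 to 32.9%) to 61.7% of 128 reads with rapamycin without serum replicate 2 (53.1 to 69.7%). The position was listed in uninduced replicate 2 at 21.2% of 52 reads (12.2 to 34.0%) and in no other control. Adar, the gene of the fused enzyme, was listed only in uninduced replicate 2, at 4 positions with 10.2 to 12.5% editing; reads of these genes can come from the plasmid. GFP alone gave 8 sites, hyperADARcd alone 112 and 14, the uninduced fusion 26 and 67, and the induced fusion with DMSO 694 and 1788. Replicate 2 of hyperADARcd alone listed only sites of at least 20%, a minimum at which the pair gave 17 and 14. All 8 induced libraries listed more sites than any of the 4 libraries of enzyme alone or uninduced fusion, 48.2-fold more by geometric mean. Their exact permutation p was 0.00404, the smallest that the 495 splits allow. Of the 8 induced libraries 6 had an inhibitor, and the uninduced fusion also carries 4E-BP. The pooled test thus mixes attachment, induction and treatment. With DMSO alone the fold was 27.1 against hyperADARcd alone and 26.0 against the uninduced fusion, each with an exact permutation p of 0.333, the smallest possible for 2 libraries against 2. With a replicate left out in turn these folds ranged from 9.87 to 74.3 and from 16.2 to 41.8, and at a minimum level of 20% they were 19.4 and 44.2.

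**Figure D1:**
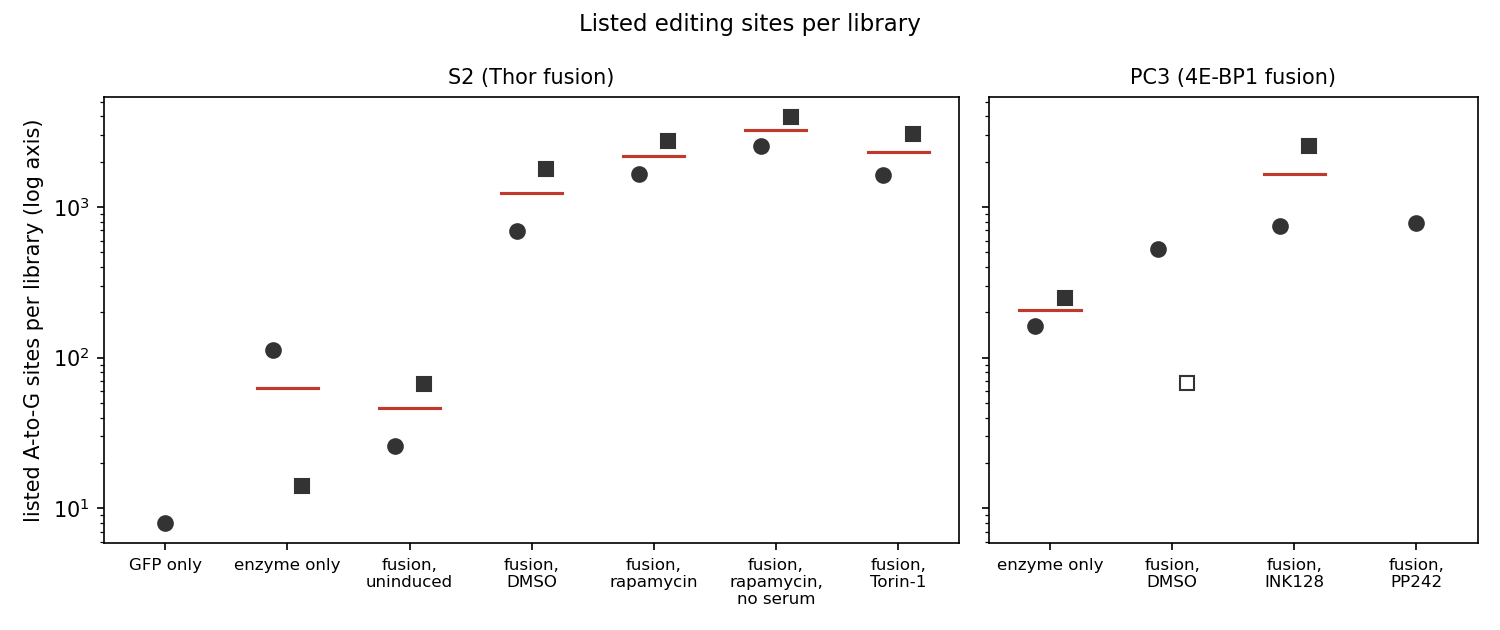
Listed edited sites per library on a log axis, by group in S2 and PC3; circles are replicate 1, squares replicate 2, and red lines the mean of the group. The open square is the shortened list of PC3 4E-BP1 with DMSO replicate 2, and the 8 induced S2 libraries lie between 694 and 3981 sites.

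With DMSO, 304 S2 genes had 342 target sites, found in both replicates and absent from GFP alone and hyperADARcd alone. PPO1 (dm3 2R:13774817-13777428), a prophenoloxidase of the fly melanization response, had 4 target sites with a mean level of 31.8% ± 7.00 (SD, n = 2). The small ribosomal subunit gene RpS16 (2R:18493670-18495392) had 3 target sites at 29.9% ± 14.5, and CG7414, which encodes the initiation factor eIF2A, had 3 at 23.9% ± 9.96. The others with 3 target sites were CG10565 at 28.2% ± 12.4, Spp (signal peptide peptidase) at 23.6% ± 5.47, CG1882 at 22.9% ± 2.19 and CSN5, the catalytic subunit of the COP9 signalosome, at 17.98% ± 5.48. Ssrp, a subunit of the histone chaperone FACT, had 2 target sites at 42.3% ± 24.2, the alanyl-tRNA synthetase gene Aats-ala 2 at 33.0% ± 18.8, and Uba3, part of the NEDD8-activating enzyme, 2 at 31.3% ± 27.3. Of the sites listed in DMSO replicate 1, 56.1% were also listed in replicate 2, and 21.8% the other way round; for hyperADARcd alone these shares were 4.46% and 35.7%. Without DMSO replicate 1 the target genes numbered 1086 and without replicate 2 they numbered 561.

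The inhibitor groups ask which mRNAs 4E-BP meets when TOR, the kinase that phosphorylates 4E-BP and lowers its affinity for eIF4E, is inhibited. Rapamycin gave 952 target sites in 651 genes, rapamycin without serum 1172 in 850 genes, and Torin-1 886 in 552 genes. Among the 10 genes with the most target sites with rapamycin were 3 of the initiation factor eIF3: eIF3-S8 (eIF3c, 2R:13553560-13556597) had 7 target sites at 22.3% ± 0.590, eIF-3p66 (eIF3d1) 6 at 24.2% ± 1.29, and eIF3-S10 (eIF3a) 5 at 34.9% ± 0.793. With Torin-1, eIF3-S8 again had 7 target sites, at 24.3% ± 0.850, and eIF3-S10 5 at 31.5% ± 4.35. The elongation factor genes Ef1gamma (6 target sites at 23.3% ± 3.42 with rapamycin) and Ef1alpha48D (5 at 30.3% ± 3.78 with Torin-1) were also among the 10 genes with the most sites. With Torin-1, CG7414 (eIF2A) had 6 target sites at 29.0% ± 2.27, RpS16 6 at 27.97% ± 1.78 and RpL7, of the large subunit, 6 at 20.5% ± 0.461. Each group's mean covers its own target sites, so these means are not a test of a change in level.

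The tetraspanin gene Tsp42Ee (2R:2900560-2905827) had 6 target sites with rapamycin (26.8% ± 0.659), 7 without serum (26.1% ± 12.7) and 7 with Torin-1 (26.4% ± 1.85), against 1 with DMSO. Catsup, a ZIP-family zinc transporter, had 6 target sites with rapamycin (33.1% ± 2.17), 4 without serum (40.1% ± 9.29) and 5 with Torin-1 (41.4% ± 1.39). Spp had 5 in each inhibitor group, at 30.7% ± 5.24, 37.0% ± 7.11 and 35.7% ± 3.02 in the same order. PPO1 had 5 target sites with rapamycin at 58.4% ± 9.75 and 5 without serum at 39.1% ± 14.0. With rapamycin, the DEAD-box helicase gene Rm62 had 6 at 30.1% ± 1.52 and betaTub60D, a beta tubulin, 6 at 22.8% ± 2.18. Without serum, CG10565, Uba3, GstO2 (an omega-class glutathione transferase), eIF3-S10 and Sra-1 (Cyfip, of the WAVE complex) had 4 each, with means from 30.8% to 37.3%, and CG7414 had 6 at 24.7% ± 8.52. GstO2 had 5 with Torin-1 at 27.5% ± 1.41.

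The S2 groups shared many targets. Rapamycin and Torin-1 shared 406 target genes where 117 would be shared if drawn independently from the 3061 listed genes, and 530 target sites against 101. Of the 304 DMSO target genes, 190 (62.5%) were targets with rapamycin, 241 (79.3%) with rapamycin without serum and 149 (49.0%) with Torin-1. In all 3 inhibitor groups 312 genes were targets; 182 of these were no target with DMSO, but only 30 were listed in no DMSO library. The independent draw takes no account of coverage, and overlap at equal coverage was not tested. Inhibitor libraries listed 2.22-fold more sites than DMSO libraries, with an exact permutation p of 0.214 where 0.0714 is the smallest possible; without DMSO replicate 1 the fold was 1.38 and without replicate 2 it was 3.56. At a minimum level of 20% it was 2.71 and in thinned reads 2.68, both with an exact permutation p of 0.0714. Thinning could only remove listed sites and left Torin-1 replicate 1 whole, which can raise the thinned fold. Replicate 2 listed more sites than replicate 1 in each induced group, which this test counts as spread. Within each replicate number every inhibitor library listed more sites than DMSO. Whether replicate numbers pair libraries is not known. Torin-1 and rapamycin, at the same dose and time, differed 1.04-fold in site number, and serum withdrawal with rapamycin 1.49-fold (exact permutation p of 1 and 0.667 for 2 against 2).

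Editing levels could be compared at 148 positions in 124 genes that were listed in all 8 induced libraries; 127 of these positions were listed in neither library of hyperADARcd alone. The median level was 17.2% and 30.8% with DMSO, 40.1% and 39.4% with rapamycin, 28.7% and 46.1% with rapamycin without serum, and 45.3% and 40% with Torin-1. The inhibitor libraries averaged 15.9 percentage points above DMSO, and 5 of 6 lay above the higher DMSO library. The exact permutation p was 0.143, and with 0.0714 the smallest possible for 6 against 2 this test could not have passed 0.05 at any shift.

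**Figure D2:**
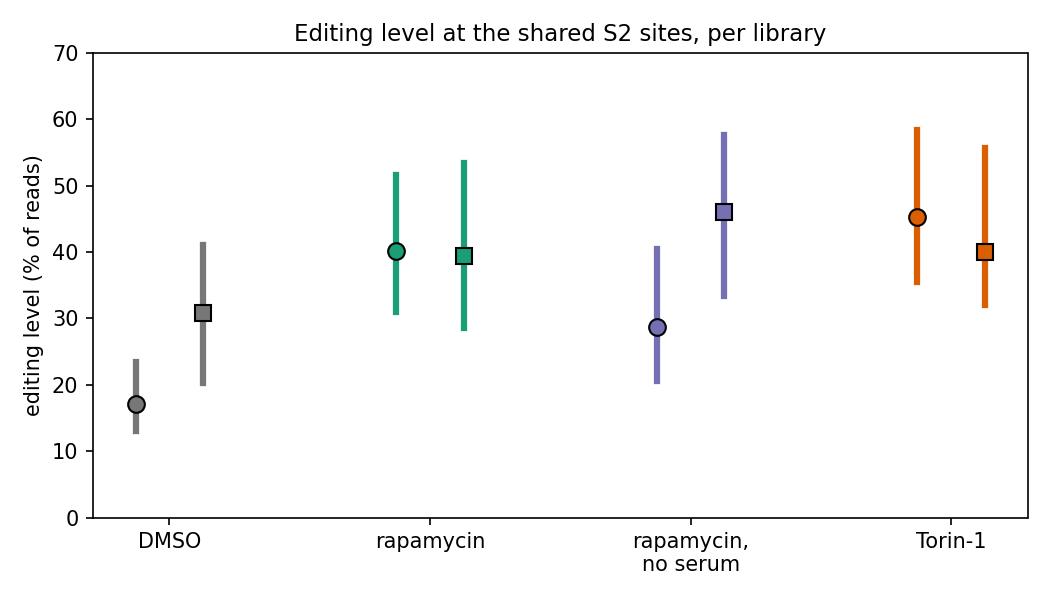
Editing level in percent at the 148 positions listed in all 8 induced S2 libraries, by group; points are the median of each library (circle for replicate 1, square for replicate 2), and bars span its quartiles. DMSO medians are 17.2% and 30.8%.

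Rapamycin against DMSO asks how inhibition of TOR complex 1 changes editing of single mRNAs. VhaAC45 (2R:5096236), an accessory subunit of the vacuolar ATPase, rose from 48.0% ± 4.16 to 87.5% ± 3.18 (SD, n = 2 each; log2 odds ratio 2.93, SE 0.67, edgeR adjusted p = 0.00186). It was the only gene of 124 called by edgeR, and limma called 4. With the sites of the enzyme-only libraries left out edgeR called no gene, and with at least 40 reads in every library it called no position. At single positions 6 of 148 rose and 0 fell, with 44 higher and 0 lower at an unadjusted p under 0.05, and limma called 7 positions. Without DMSO replicate 1 edgeR called 0 positions, over these 148 or over the 309 of the other 7 libraries. The median log2 odds ratio was 1.08 and 138 positions were higher. PPO1, the only hemocyte marker tested, had a log2 odds ratio of 2.22. Its unadjusted edgeR p was under 0.05, but it was not called over all genes. With library medians made equal no position rose and 2 fell, VhaAC45 had a log2 odds ratio of 1.84 (adjusted p = 0.160), and the common shift of about 1.08 was removed.

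Rapamycin without serum against DMSO combines inhibition of TOR complex 1 with serum withdrawal. In 9 genes the level rose, and 2 of these encode subunits of the COPI coat of Golgi vesicles: zetaCOP (3L:16666493) from 18.01% ± 1.57 to 46.1% ± 8.11 and deltaCOP (X:1753805) from 16.9% ± 7.98 to 43.8% ± 2.95. Ntf-2 (X:20906608), which imports Ran into the nucleus, rose from 41.0% ± 21.5 to 74.9% ± 4.09, and VhaAC45 to 80.5% ± 0.731. RpA-70 (3R:4089771), the large subunit of replication protein A, rose from 26.9% ± 12.7 to 58.2% ± 0.0491, and Tcp-1eta (3R:4627714), of the cytosolic chaperonin, from 19.2% ± 0.342 to 50.4% ± 10.3. The dynein light chain gene robl (2R:13344167) rose from 12.3% ± 0.637 to 40.5% ± 8.52, CG2310 from 12.4% ± 2.97 to 39.5% ± 15.9, and rush, a FYVE-domain protein of endosomes, from 13.6% ± 3.22 to 39.2% ± 15.3. The log2 odds ratios of the 9 genes lay between 1.94 and 2.26, with edgeR adjusted p from 0.0245 to 0.0399. At single positions edgeR called 12 higher and 0 lower (34 at an unadjusted p under 0.05) and limma called 1 position and no gene. No position and no gene was called with library medians made equal, with both groups fitted alone, in 287 positions, or without DMSO replicate 1.

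Torin-1 against DMSO gave the most calls: 22 genes rose and 0 fell. Fewer genes were called with the sites of the enzyme-only libraries left out, or with at least 40 reads in every library. CG16817 (3R:5504555-5504609) rose from 22.0% ± 0 to 63.5% ± 5.23 (log2 odds ratio 2.61, SE 0.78, edgeR adjusted p = 0.0193). The importin gene msk (3L:8112479) rose from 29.3% ± 8.65 to 69.3% ± 6.03, and robl from 12.3% ± 0.637 to 46.0% ± 1.46. CG14476 rose from 38.8% ± 14.8 to 77.8% ± 7.21, VhaAC45 from 48.0% ± 4.16 to 81.4% ± 0.612, and Catsup from 27.2% ± 15.8 to 60.4% ± 3.61. Cortactin (3R:16888302), an actin-binding protein, rose from 33.9% ± 6.47 to 68.4% ± 3.91. Nurf-38 (2R:20447861), the pyrophosphatase of the nucleosome remodeling factor NURF, rose from 33.7% ± 10.5 to 67.0% ± 10.4. CG9917 rose from 44.6% ± 4.21 to 76.2% ± 9.52 and CG2310 from 12.4% ± 2.97 to 43.7% ± 7.68. At single positions edgeR and limma each called 27 higher and 0 lower, with 56 by edgeR at an unadjusted p under 0.05, and the median log2 odds ratio was 1.27. No position was called once library medians were made equal, nor without DMSO replicate 1 over the 309 positions of the other 7 libraries (33 higher at an unadjusted p under 0.05).

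**Figure D3:**
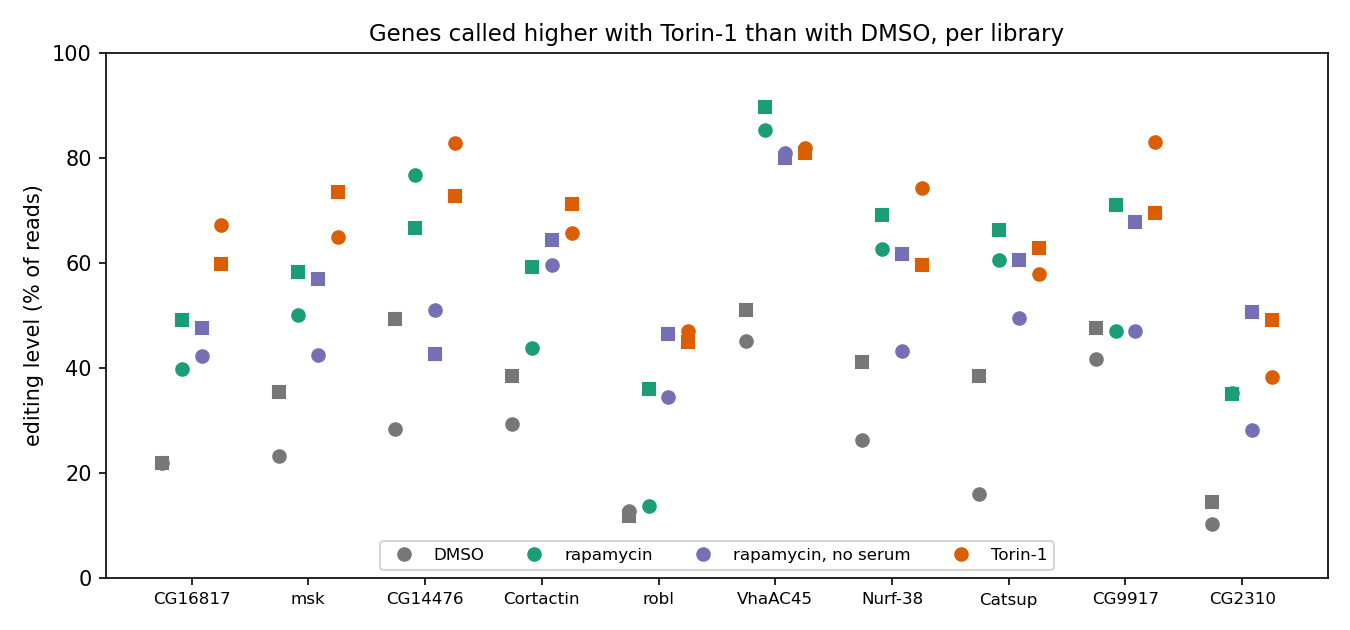
Editing level in percent, by library, of the 10 genes with the largest rise with Torin-1 against DMSO among those called; circles are replicate 1 and squares replicate 2, and colours mark the treatment. CG16817 has DMSO replicates at 22.0% and a Torin-1 mean of 63.5%.

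Torin-1 against rapamycin compares a kinase-site inhibitor with the allosteric one at the same dose and time. No position and no gene was called by edgeR; 2 positions were higher and 0 lower at an unadjusted p under 0.05, and limma called none. The median log2 odds ratio was 0.14, and the median 95% interval of a position ran from -1.27 to 1.61, so differences of several fold in odds were not excluded at most positions. Intervals at 146 of 148 positions included 0. Serum withdrawal during rapamycin gave 0 calls by edgeR and limma, with 0 higher and 4 lower by edgeR at an unadjusted p under 0.05 and a median log2 odds ratio of -0.25. Changes against DMSO were correlated across the 148 positions, with Pearson r of 0.66 for rapamycin and Torin-1, 0.56 for rapamycin with and without serum, and 0.58 for Torin-1 and rapamycin without serum. Groups without any change gave about 0.50 in simulation because they share the DMSO libraries, and positions are not independent replicates. The covariance was 0.271 for rapamycin and Torin-1 against 0.144 in simulation. With separate DMSO libraries for each treatment the r fell to 0.15 and 0.23.

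Genes of the translation apparatus were frequent among S2 target genes. With Torin-1, 48 of 66 listed cytosolic ribosomal protein genes were targets against 16.8% of other genes (odds ratio 13.2, Fisher's exact test, adjusted p = 5.62e-21). With rapamycin 44 were targets (odds ratio 7.87), with DMSO 17 (odds ratio 3.27, adjusted p = 0.000843) and without serum 25 (odds ratio 1.60, adjusted p = 0.152). RpS16 had 5 target sites with rapamycin and RpL7, RpL37A and RpL4 had 3 each; with Torin-1, RpL37A and RpL4 had 4 each. Translation factors were targets more often than other genes with DMSO (10 of 39), rapamycin (22) and Torin-1 (23, odds ratio 6.77, adjusted p = 1.62e-07). Homologues of human TOP mRNAs, transcripts whose translation depends on TOR, were targets with DMSO (9 of 16, odds ratio 12.0, adjusted p = 5.11e-05), rapamycin (11) and Torin-1 (11). Among them were Ef1gamma, Ef1alpha48D, Tctp with 3 target sites in both the rapamycin and the Torin-1 group, and CG9769 (eIF3f1) with 2 in each. Without serum neither list was called. There 17 translation factors (odds ratio 2.03, Fisher's exact test, adjusted p = 0.107) and 9 TOP homologues (odds ratio 3.37, adjusted p = 0.0771) were targets.

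Oxidative phosphorylation genes were targets more often than other genes with rapamycin (29 of 65, odds ratio 3.07) and Torin-1 (32 of 65, odds ratio 4.62, adjusted p = 1.29e-07). They were not called without serum (25 of 65, odds ratio 1.64, Fisher's exact test, adjusted p = 0.152). CoIV, a cytochrome c oxidase subunit, had 4 target sites with Torin-1 at 24.9% ± 3.80, and the ATP synthase genes ATPsyn-gamma, CG4692 (ATPsynF) and ATPsynG had 2 each. Proteasome genes were called with Torin-1 (15 of 31, odds ratio 4.35), but not when a target gene needed at least 2 sites (odds ratio 0.432) or over 3 strata of coverage (odds ratio 1.08), with Prosalpha3 at 3 target sites, and Rpn10, Prosalpha7 and Prosalpha6 at 1 each. Chaperones were called with DMSO (7 of 26, odds ratio 3.40, adjusted p = 0.0476) and Torin-1 (13 of 26, odds ratio 4.63); CG8258 (CCT8), Hsc70-4 and Hsp83 had 3 target sites each with Torin-1 and Cct1 had 2. In all, 14 of 60 tests of lists and groups were higher and none was lower. Coverage differed between lists: the median over genes of the highest site coverage was 123 reads for ribosomal proteins, 81 for translation factors, 98.5 for the TOP homologues and 33 for genes outside a list. In an exact test over 3 strata of coverage 3 of the 14 were called: ribosomal proteins with rapamycin (odds ratio 2.47) and Torin-1 (odds ratio 4.04, adjusted p = 0.000184), and TOP homologues with DMSO (odds ratio 5.47, adjusted p = 0.0279). Strata of this width do not remove coverage: simulated targets set by coverage alone gave a call for ribosomal proteins in 20 of 20 draws over 3 strata (median odds ratio 4.23) and in 0 over 10. Over 10 strata none of the 60 was called, and the odds ratio of ribosomal proteins with Torin-1 was 1.30. Coverage is known only at listed sites, so genes edited at more sites can rank higher. Strata of such coverage may also remove part of a real difference.

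**Figure D4:**
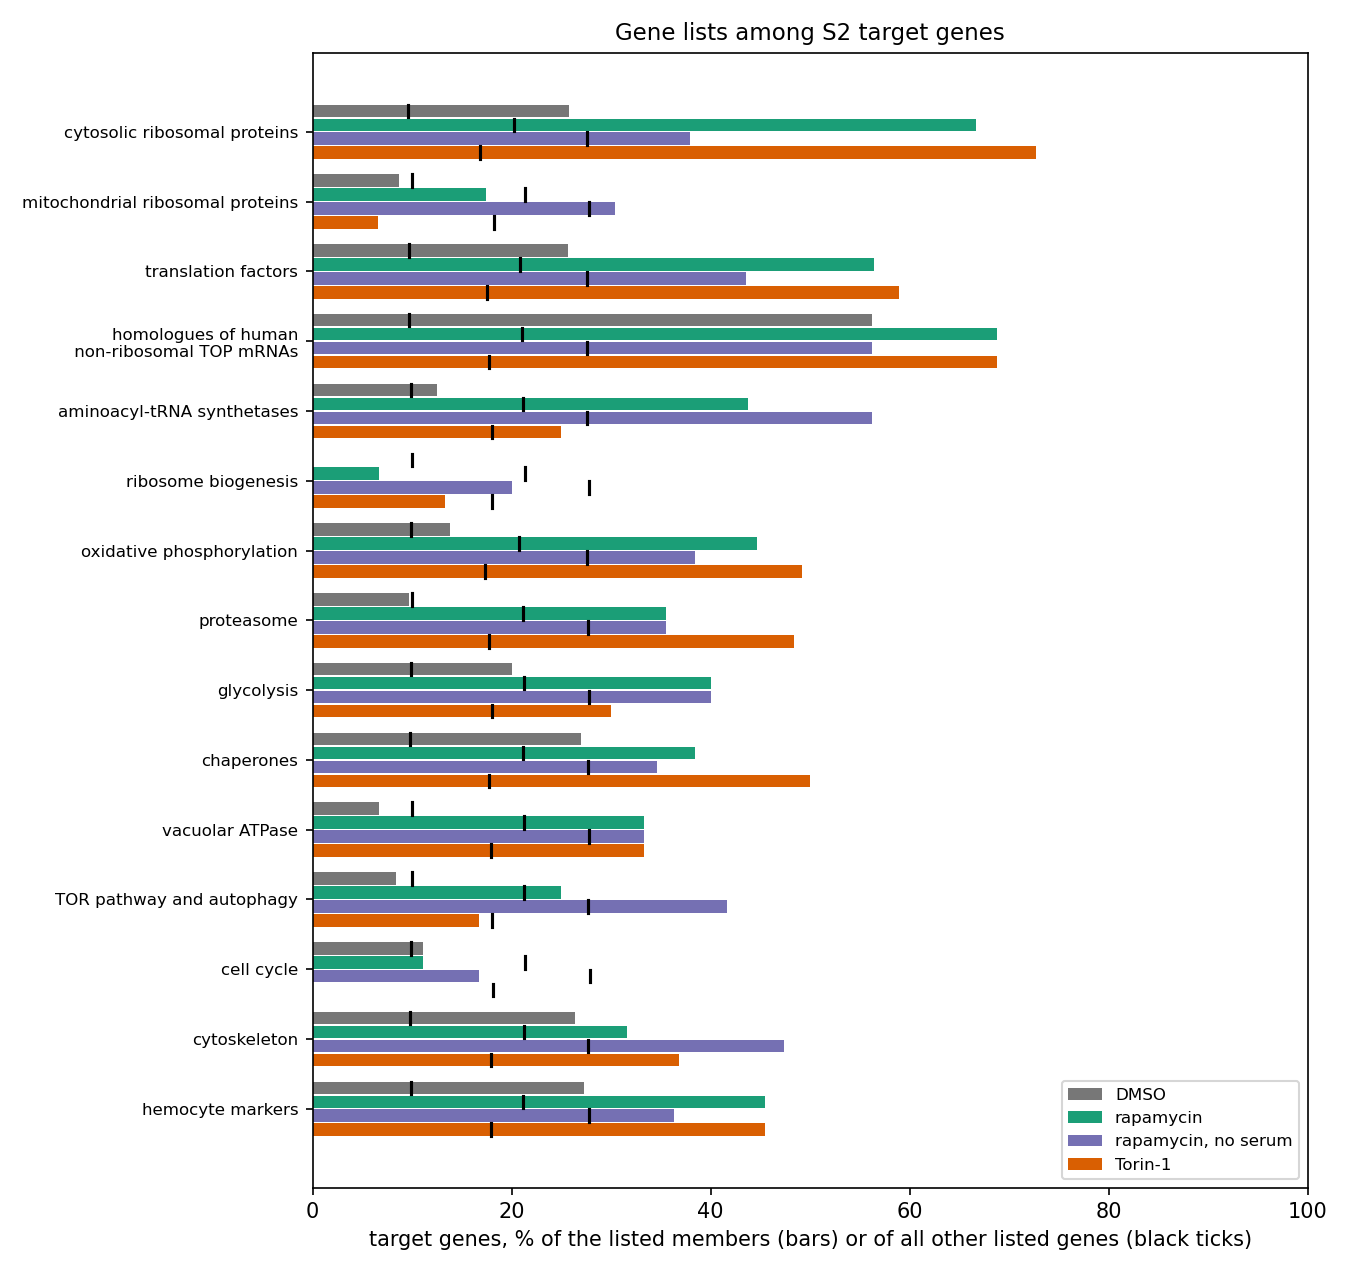
Percent of the listed members of each S2 gene list that were target genes (bars, coloured by treatment), with black ticks for the percent among all other listed genes of the same treatment. With Torin-1, 72.7% of cytosolic ribosomal protein genes were targets against 16.8% of other genes.

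The remaining S2 lists gave no call in any group. Mitochondrial ribosomal proteins were targets in 8 of 46 genes with rapamycin, 14 without serum and 3 with Torin-1 (odds ratio 0.313, adjusted p = 0.144); mRpS22 and mRpS9 had 3 target sites each with rapamycin. Of 16 aminoacyl-tRNA synthetases 9 were targets without serum (odds ratio 3.37, adjusted p = 0.0771) and 7 with rapamycin, where Aats-asn had 4 target sites and Aats-tyr and Aats-thr 3 each. Ribosome biogenesis genes were targets in at most 3 of 15, among them Non1 with 5 target sites with Torin-1. Glycolysis genes were targets in at most 4 of 10; Gapdh2 had 5 target sites with Torin-1 at 26.1% ± 0.729 and none with DMSO. Vacuolar ATPase genes were targets in 5 of 15 in each inhibitor group, TOR pathway and autophagy genes in at most 5 of 12, which include Thor itself and Atg4a, and cell cycle genes in at most 3 of 18, with polo at 3 target sites without serum. Cytoskeleton genes reached 9 of 19 without serum (odds ratio 2.36, adjusted p = 0.152), with betaTub60D and Arpc2 at the front. Hemocyte markers, expressed by S2 cells themselves, reached 5 of 11 with rapamycin and with Torin-1, where vkg and Cg25C, the collagen IV genes, had 5 and 4 target sites. Of germline and ovary markers 1 was listed and 0 were targets, and no neuron marker was listed.

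Levels were also compared within the lists. Of 17 ribosomal protein genes tested, 0 were called in any of the 5 comparisons, by edgeR over all genes or adjusted over the list alone; 16 were higher with rapamycin and 16 with Torin-1 than with DMSO. Of 10 translation factors, all 10 were higher with each inhibitor than with DMSO; edgeR called 1 with Torin-1 over all genes and 0 adjusted over the list alone. Over the list alone 1 translation factor was called with rapamycin. Of 4 TOP homologues 1 was called with Torin-1 both ways. Of 5 oxidative phosphorylation genes 0 were called, and all 5 were higher with each inhibitor. The other tested genes were raised too, so these counts do not set the lists apart. Ribosomal proteins had median log2 odds ratios of 0.964 with rapamycin and 0.985 with Torin-1, against 1.08 and 1.28 for other genes. Translation factors had 1.18 with rapamycin, 0.324 without serum and 1.24 with Torin-1, against 1.06, 0.923 and 1.26. Of 4 chaperones 1 was called without serum over all genes, Tcp-1eta, and adjusted over the list alone 1 with rapamycin, 2 without serum and 2 with Torin-1. Camera found ribosomal proteins less raised than the other genes without serum against DMSO (adjusted p = 0.0210); with an estimated correlation the adjusted p = 0.833. It found translation factors lower without serum than with serum under rapamycin (all 10 genes lower, adjusted p = 0.0317); with an estimated correlation the adjusted p = 0.930.

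The annotation of the lists separates exons from introns only. All target sites with DMSO (342), rapamycin (952) and Torin-1 (886) were exonic, as were 1171 of 1172 without serum and 120 of 121 sites of hyperADARcd alone. In PC3 382 of 385 INK128 target sites and 681 of 694 with PP242 were exonic, against 326 of 336 with the enzyme alone. No group differed from the enzyme alone by Fisher's exact test (smallest p = 0.0455, all adjusted p = 0.267).

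In PC3 the same question was asked of human 4E-BP1. The enzyme alone listed 163 and 250 sites, the fusion with DMSO 529 in its complete library, with INK128 754 and 2549, and with PP242 789. The 4 complete fusion libraries listed 4.67-fold more sites than the enzyme alone, with an exact permutation p of 0.133, the smallest possible; the fold was 2.61 at a minimum level of 20% and 7.66 at 40 reads. On chromosome 6, which the shortened list also covers, the 5 fusion libraries listed 39 to 140 sites against 24 and 31, 2.04-fold more (exact permutation p of 0.0952, the smallest possible), or 1.37-fold at the minimum of 20% (p = 0.381). The fusion listed 39 and 54 sites there with DMSO, 50 and 140 with INK128 and 39 with PP242. Inhibitor and DMSO libraries thus overlapped on this chromosome. ADARB1, which encodes ADAR2, had a site at hg38 21:45220941 in DMSO replicate 1 (14.2%, Wilson interval 9.04 to 21.5%) and with PP242 (19.0%, 13.0 to 26.9%). EIF4EBP1, which encodes 4E-BP1, had a site at 8:38059965 in both INK128 libraries (13.6% and 15.6%). The background of sites is not small here: 47.2% of sites of enzyme alone replicate 1 were found again in replicate 2.

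Both DMSO lists of PC3 shared 9 target sites in 9 genes, all on chromosomes 6 and 7. PPP1R18, a regulatory subunit of protein phosphatase 1, was edited at 30.9% ± 14.2 (SD, n = 2), and the kinase gene PIM1 at 30.5% ± 2.73. RPL10A, of the large ribosomal subunit, was at 27.0% ± 0.789, HIBADH, of valine breakdown, at 24.8% ± 9.87 and ZFAND3 at 23.2% ± 14.3. PERP (17.4% ± 6.15), the bromodomain gene BRD2 (16.6% ± 0.606), the cytokine gene IL6 (12.8% ± 3.90) and POLD2 (12.1% ± 2.68), of DNA polymerase delta, completed the set. In DMSO replicate 1 alone there were 397 such sites in 346 genes. INK128 gave 385 target sites in 350 genes. PAICS (4:56459990-56460950), of purine synthesis, had 4 at 16.3% ± 3.29, GATC, of the mitochondrial glutamyl-tRNA amidotransferase, 3 at 36.4% ± 3.64, and SOD2, the mitochondrial superoxide dismutase, 3 at 14.2% ± 1.84. MED21, FTL (ferritin light chain), NEFL (neurofilament light chain), PSMD3 (a proteasome subunit), DNM2, DDA1 and PI3 had 2 each, with means from 25.1% to 30.7%.

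PP242, in a single library, gave 694 sites outside the enzyme-only lists in 591 genes. The transcription factor gene JUN (1:58782605-58783727) had 5, with 16.7% of 150 reads edited (Wilson interval 11.6 to 23.4%), and EIF2S3, of initiation factor eIF2, had 5 with 13.5% of 156 reads (8.98 to 19.7%). FCF1, of the small-subunit processome, had 4 with 43.0% of 86 reads (33.1 to 53.6%), and PAICS 4 with 20.7% of 140 reads (14.8 to 28.2%). These reads are summed over a gene's sites, so a read over several sites counts at each and the intervals can be too narrow. MRPS16, PPP1R18 and SNAPC1 had 4 each, and FTL, G0S2 and SLC4A2 had 3 each. INK128 and PP242 shared 213 genes where 97.2 would be shared if drawn independently from the 2129 listed genes.

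INK128 (sapanisertib) and PP242 (torkinib) share a pyrazolopyrimidine amine core and differ in its aryl group; the doses differed, so their values stand side by side. At 7 positions in 6 genes listed in all 5 fusion libraries edgeR called nothing for INK128 against DMSO (1 higher and 0 lower at an unadjusted p under 0.05; limma 0 calls), for PP242 against DMSO (0 and 0; limma 0) or for PP242 against INK128 (0 and 0; limma 0). RPL7L1 (6:42888592) had 28% and 21.7% with DMSO, 53.1% and 41.5% with INK128 and 42.9% with PP242, and PIM1 (6:37174144) had 28.6% and 32.4%, 12.8% and 20.3%, and 12.8%. At 149 positions in 117 genes of the 4 complete libraries the median level was 17.8% with DMSO, 22.2% and 30.6% with INK128 and 24.0% with PP242. Here PAICS, over 6 positions, was called higher with INK128, from 24.5% (19.9 to 29.9%) in the DMSO library to 37.5% ± 4.51 (n = 2; log2 odds ratio 0.88, SE 0.24, edgeR adjusted p = 0.0446). The test assumes that the single DMSO library varies as the INK128 pair does. Not all 6 positions were target sites: PAICS had 4 target sites with INK128, at a mean level of 16.3%. The other tested positions were therefore also listed with the enzyme alone, and the call does not rest on target sites only. PAICS was the only gene called and had 33.0% (27.3 to 39.4%) with PP242; with library medians made equal its log2 odds ratio was 0.16. PP242 and INK128 differed by a median log2 odds ratio of -0.16, the median 95% interval ran from -2.38 to 1.97, and edgeR called 0 positions and 0 genes, with 1 position higher and 0 lower at an unadjusted p under 0.05.

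Gene lists among PC3 target genes gave 0 calls in 45 tests after adjustment. The DMSO tests had only the 9 target genes left by the shortened list. Of these, 1 was a ribosomal protein gene and none was in another tested list, so those tests could hardly call a list. They enter the adjustment all the same, so the adjusted p-values with INK128 and PP242 depend on counting them. With PP242, non-ribosomal TOP mRNAs came closest (6 of 7, odds ratio 15.8, adjusted p = 0.0578), with EEF1A1 at 3 sites, EEF2 and VIM at 2 and RACK1 at 1; with INK128 4 of the 7 were targets. Translation factors were targets in 13 of 23 genes with PP242 (odds ratio 3.44, adjusted p = 0.0578) and 9 with INK128. EIF2B2 was a target with both, at 1 and 2 sites. The 9 include EIF4EBP1, the gene of the fused protein, whose reads can come from the construct. Oxidative phosphorylation genes were targets in 13 of 23 with PP242 and 8 with INK128, with NDUFB11 at 2 sites in both. Of 18 cytosolic ribosomal protein genes 9 were targets with PP242 and 5 with INK128, which include RPL10A, FAU and RPL17, and of 25 mitochondrial ones 12 and 5. Of 8 eIF4E-sensitive mRNAs 5 were targets with PP242, among them MYC, MCL1, ODC1 and CCND3 at 1 site each (odds ratio 4.37, adjusted p = 0.189), and 1 with INK128. Without INK128 replicate 2, 4 of the 45 tests were called.

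The other PC3 lists gave no call, and their shares lay on both sides of those of other genes. With INK128 the odds ratio was 3.28 for cytoskeleton and 3.67 for aminoacyl-tRNA synthetases (Fisher's exact test, adjusted p = 0.141 and 0.189). It was 0 for chaperones and for cell cycle genes. With PP242 and INK128, the numbers of target genes were 5 and 5 of 12 aminoacyl-tRNA synthetases (KARS and LARS among them), 3 and 3 of 8 ribosome biogenesis genes (EIF6, NOP58, UTP4), and 3 and 3 of 15 proteasome genes. They were 3 and 2 of 5 glycolysis genes (GPI and TPI1), 4 and 0 of 12 chaperones, and 2 and 1 of 5 vacuolar ATPase genes. They were 4 and 1 of 13 mTOR pathway and autophagy genes, 2 and 0 of 8 cell cycle genes, and 9 and 7 of 18 cytoskeleton genes, with FLNA at 3 sites with PP242 and KRT7 at 2 with INK128. The single listed marker of epithelium and prostate was KRT19, a target with PP242, and that of stroma and blood was CD68, a target with both inhibitors.

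Across lines, 53 of 66 ribosomal protein genes were targets in any S2 inhibitor group and 5 of 18 with INK128 in PC3. Translation factors gave 27 of 39 and 9 of 23, oxidative phosphorylation 39 of 65 and 8 of 23, and chaperones 14 of 26 and 0 of 12. No family differed between the lines by an exact test of the odds relative to other genes (14 families, smallest p = 0.0519 for ribosomal proteins, adjusted p = 0.454). The lines differ in constructs, inhibitors and depth.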

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

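The gene lists were compared between each pair of S2 groups with Fisher's exact test of the difference between 2 groups, and the tests weighed in the paragraph on ribosomal proteins without serum were chosen after these differences were seen. In each case the test asks whether members that were targets in only 1 of the 2 groups fell on 1 side more often than other genes did, and p-values are adjusted over 90 comparisons.

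Cytosolic ribosomal protein genes differed in 3 pairs of groups. Between DMSO and Torin-1, 31 ribosomal protein genes were targets with Torin-1 only and 0 with DMSO only, against 372 and 155 other genes (adjusted p = 0.00126). Between rapamycin and rapamycin without serum, 20 were targets with serum only and 1 without serum only, while other genes went the other way, 188 and 406 (adjusted p = 1.35e-07). Between Torin-1 and rapamycin without serum, 25 were targets with Torin-1 only and 2 without serum only, against 158 and 479 other genes (adjusted p = 5.29e-11). The log2 odds of this difference were 4.95, against 3.13 without Torin-1 replicate 1 and 5.33 in thinned reads. Torin-1 replicate 1 was the shallowest induced library. At the 148 shared positions its median coverage was 0.65 times the mean of the induced libraries for other genes and 0.906 times for ribosomal proteins. Whether this uneven coverage raised the ribosomal share was not tested. The difference between DMSO and Torin-1 was lost without DMSO replicate 1 (Fisher's exact p = 0.147) and without Torin-1 replicate 1 (p = 1), at a minimum level of 20% (p = 0.0898) and in thinned reads (p = 0.0605). That between rapamycin with and without serum was lost without rapamycin replicate 1 and without replicate 1 of rapamycin without serum. Its log2 odds moved from -4.88 to -1.51 and -1.98 in turn. In the latter case 56 ribosomal protein genes were targets without serum against 44 with serum, where a single library need not repeat a site. Genes that were targets with Torin-1 and not without serum, chosen after these values were seen, include RpL28 and RpL14, with 3 target sites each with Torin-1, and RpL22 with 2.

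Translation factors and oxidative phosphorylation genes differed between Torin-1 and rapamycin without serum. Of the translation factors, 8 were targets with Torin-1 only and 2 without serum only, against 175 and 479 other genes (adjusted p = 0.0140). Among the 8, also chosen after the values were seen, were the eIF3 genes CG5642 (eIF3l) and eIF-3p40 (eIF3h), with 2 target sites each with Torin-1. Of the oxidative phosphorylation genes, 11 were targets with Torin-1 only and 4 without serum only, against 172 and 477 other genes (adjusted p = 0.00568). Among the 11, chosen in the same way, were CG9603 (COX7A) with 2 target sites with Torin-1 and ATPsyn-d with 1. Without replicate 1 of rapamycin without serum Fisher's exact p was 0.318 for translation factors and 0.121 for oxidative phosphorylation, without Torin-1 replicate 1 it was 0.241 and 0.0964, and in thinned reads 0.201 and 0.0725. For oxidative phosphorylation it was 0.341 at 40 reads and 0.338 at a minimum level of 20%.

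Replicate 1 without serum listed 29 of 66 ribosomal protein genes, where the other inhibitor libraries listed 48 to 62. Low coverage in that replicate remains open: its coverage was 0.963 times that in the other libraries, but only at the 21 of 73 well covered ribosomal protein positions that it listed, and its coverage at the others is not known. Editing near the deposited minimum of 10% also remains open, since the positions it did not list had a median level of 15.6% elsewhere against 30.1% for those it listed, and a gap in the same direction was seen in every induced library, larger in DMSO replicate 1 (16.4% and 41.4%) and smaller in the others. It listed 28.8% of well covered ribosomal protein positions and 46.9% of other well covered positions (Fisher's exact test, adjusted p = 0.244). Replicate 1 alone and serum withdrawal cannot be told apart, because without it a single library stands for serum withdrawal, where Fisher's exact test gave p = 0.00654 against Torin-1 and p = 0.325 against rapamycin with serum.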

How the results depend on the processing

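Counts of target sites depended strongly on thresholds, and level changes against DMSO on the DMSO libraries. Depth and the editing minimum limit these results, because a position is listed only with at least 20 reads and 10% editing, so absence from a list is not absence of editing. Equal library medians, the analysis without DMSO replicate 1 over 309 positions, the lists within 10 strata, the 20% minimum for lists, the complete PC3 libraries and the separate DMSO libraries were chosen after the data were seen. Where a result changed below, the cause was not tested unless given. Among comparisons, 303 values under alternatives were classed as the same, 132 as moved and 4 as reversed. The rule for these classes differed with the kind of value, so 303 is not a count of values within 1.5-fold. A fold of listed sites was classed as the same if its direction and its side of the p-value threshold were kept, whatever its size. Of log2 odds ratios of named genes, 85 kept their call and 113 became weaker, and none reversed. The alternative of at least 40 reads in every library gave no value for PC3 levels, and listing in at least 1 replicate none for PP242, which has a single library.

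With at least 40 reads, target sites with DMSO, rapamycin, rapamycin without serum and Torin-1 in S2 numbered 139, 398, 418 and 337, in 127, 282, 327 and 204 genes; in PC3 with DMSO, INK128 and PP242 they numbered 2, 135 and 177, in 2, 129 and 160 genes. With at least 20% editing they numbered 93, 366, 418 and 331 in 93, 303, 361 and 261 S2 genes, and 3, 73 and 145 in 3, 73 and 140 PC3 genes. Listing in at least 1 replicate gave 2013, 3345, 5205 and 3692 sites in 1290, 1705, 2537 and 1723 S2 genes, and with DMSO and INK128 in PC3 450 and 2585 sites in 388 and 1872 genes. With at least 2 target sites per gene, 43, 212, 252 and 218 S2 genes and 0, 44 and 90 PC3 genes were left. Thinned to the shallowest fusion library, S2 target sites with DMSO, rapamycin, rapamycin without serum and Torin-1 numbered 166, 623, 546 and 781, in 150.5, 437, 434 and 503 genes, so that Torin-1 had the most and not the fewest of the inhibitor groups. The minimum of 2 sites per gene lowers these counts by construction. The others need not, since they apply to the control libraries too, and thinned PP242 had 708 sites in 597.5 genes.

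Leaving out each replicate in turn, S2 target sites ranged from 342 to 1719 with DMSO (304 to 1086 genes), 952 to 2676 with rapamycin (651 to 1552 genes), 1172 to 3906 without serum (850 to 1955 genes) and 886 to 2980 with Torin-1 (552 to 1618 genes). In PC3 they ranged from 9 to 397 with DMSO (9 to 346 genes) and 399 to 2324 with INK128 (360 to 1728 genes). A single replicate need not repeat a site, which raises these counts. The fold of site numbers between Torin-1 and rapamycin ranged from 0.761 to 1.42.

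Level changes against DMSO in S2 also depended on the processing. In replicates left out in turn, calls with rapamycin ranged from 0 to 38 positions and 0 to 39 genes, without serum from 0 to 34 positions and 0 to 26 genes, and with Torin-1 from 0 to 53 positions and 0 to 60 genes; a lone library is assumed to vary like the other groups. Without DMSO replicate 1 over the positions listed in the other 7 libraries, 0 positions and 0 genes were called with each inhibitor. With library medians made equal, the median log2 odds ratio became -0.01 with rapamycin (-0.00834) and -0.01 without serum (-0.00997); with rapamycin 2 positions and 1 gene were called, all lower, and without serum and with Torin-1 0 positions and 0 genes. The setting removes a shift common to all positions by construction. With at least 40 reads in every library 0 positions were called with rapamycin, 0 positions and 0 genes without serum, and 1 position and 1 gene with Torin-1, among 59 positions. With the sites of the enzyme-only libraries left out, 3 positions and 0 genes were called with rapamycin and 13 genes with Torin-1. By limma 4 genes were called with rapamycin, and 1 position and 0 genes without serum. Both groups fitted alone gave 0 positions and 0 genes without serum. With a replicate block, which pairs libraries by replicate number, 15 positions and 7 genes were called with rapamycin. In the complete PC3 libraries 1 gene was called with INK128.

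The correlation of changes across positions fell when each treatment had its own DMSO library: rapamycin with and without serum 0.211 and 0.0567, Torin-1 and rapamycin without serum 0.175 and 0.0942, rapamycin and Torin-1 0.148 and 0.228, for the 2 ways of splitting. Sharing DMSO libraries raises it by construction. Of the 60 tests of S2 lists, 3 were called over 3 strata of coverage, 0 over 10 strata and 8 with at least 20% editing. The odds ratio of proteasome genes with Torin-1 was 0.432 when a target gene needed at least 2 sites, and their call was lost. Camera with an estimated correlation called 0 lists. Without each replicate in turn, the tests of PC3 lists called ranged from 0 to 4.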

Other observations

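Of the 312 S2 genes that were targets in all 3 inhibitor groups, 30 were listed in no DMSO library; this group and the genes named here were chosen after their values were seen, as were the tests weighed below. Pep and VhaM8.9 (the fly ATP6AP2, a vacuolar ATPase accessory protein) had the most target sites, 6 each over the inhibitor groups, with 3 each with Torin-1 at 17.8% ± 0.711 and 20.2% ± 0.654 (SD, n = 2). The group held 3 respiratory chain genes: CG9172 (ND-20, of complex I) with 2 sites with Torin-1 at 12.2% ± 2.07, CG4769 (cytochrome c1) with 2 at 13.8% ± 1.53, and Cyt-c-p (cytochrome c) with 1 at 31.5% ± 6.65. FK506-bp1 (Fkbp39), of the immunophilin family to which the receptor of rapamycin belongs, had 2 sites with rapamycin at 27.2% ± 2.96 and 1 with Torin-1 at 29.4% ± 13.2. The initiation factor gene eIF-2beta, the proteasome genes Rpn3 and PI31, and Desat1, a fatty acid desaturase, had 1 site in each inhibitor group. Most of these levels lie not far above the minimum of 10%, so absence from the DMSO lists does not show absence of editing.

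Replicate 2 of hyperADARcd alone held the 2 most deeply covered positions of the S2 lists, in CR41602 and CR40677, whose symbols mark non-coding genes. Thor had a further listed position in uninduced replicate 2, at 2L:3478653 with 10.2% of 59 reads (Wilson interval 4.74 to 20.5%). In PC3, PIM1 was lower with both inhibitors than with DMSO, at log2 odds ratios of -1.08 with INK128 and -1.59 with PP242, neither past the threshold (edgeR adjusted p = 0.243 and 0.351).

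Editing levels at the 148 shared S2 positions were higher with each inhibitor than with DMSO. Low coverage does not account for the rise with Torin-1, since its median log2 odds ratio was 1.24 over positions with at least 40 reads in every library. The other inhibitor groups were not weighed in this way. Low editing in a single DMSO library could account for part of the rise: without DMSO replicate 1 the Torin-1 median was 0.80, with 1 library left to stand for DMSO. A different amount of active fusion in each library cannot be told apart from binding to more mRNA, since either could raise many positions at once; with library medians made equal 0 positions were called higher with any inhibitor, and 2 were called lower with rapamycin. Binding of dephosphorylated 4E-BP to eIF4E is a possible biological explanation that was not tested here, and it stays open.

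Ribosomal protein genes were targets more often than other genes with rapamycin and Torin-1, and TOP homologues with DMSO. Read coverage may explain the ribosomal proteins: over 10 strata of coverage their odds ratio was 1.30 with Torin-1 and 1.21 with rapamycin. Coverage was the highest over a gene's listed sites, so genes edited at more sites can rank higher. The strata may therefore also remove part of a real difference, and they cannot decide between coverage and preferred binding. For TOP homologues with DMSO the odds ratio over the same strata was 4.38, no longer called after adjustment, and coverage and preferred binding cannot be told apart here because the reported coverage ends between 122 and 144 reads in these libraries and hides differences between abundant mRNAs.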
